A study of Mus musculus with 12 samples.

How the data were processed

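Total RNA of 3T3-L1 cells was extracted with TRIzol, checked on a Bioanalyzer and made into libraries with standard Illumina protocols, per the labels' protocols, and sequenced on an Illumina HiSeq in triplicate, per the series' design text. The induction medium held serum, insulin at 5 µg/ml, triiodothyronine at 1 nM, rosiglitazone at 1 µM, IBMX at 0.5 mM, dexamethasone at 2 µg/ml and indomethacin, and was kept on for 48 h, followed by maintenance medium with rosiglitazone, triiodothyronine and insulin, per the labels. The day of harvest is not given in the sources used here. The 12 libraries form 4 groups of 3 by line (control or LIGHT overexpression) and stage (undifferentiated or differentiated), as their labels state, and replicate numbers are those of the labels.

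The authors deposited 1 table per library with, per gene, a gene number, a symbol, a length, expected counts and FPKM, per the file headers. Expected counts are estimates that need not be whole, since reads that fit several transcripts or genes are shared between them, and 83.6% to 84.5% of the listed values of a library were whole to the 2 decimals given. FPKM, as deposited, divides by gene length and library total. The tables list only genes above 0, so a gene missing from a library was read as 0. The build was mm8, per the submitters' processing notes; the aligner and the counting program are not given in the sources used here. The tables hold no positions, and the reference at hand is of another build, so no coordinates are given. Whether the counting used strand is not given, so overlapping and antisense genes cannot be told apart, and reads shared by near-identical copies can be split between them.

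Over all libraries 18255 genes were listed, 12686 of them in all 12, and 17367 had a symbol. The other 888 were unnamed gene models, which held 4.23% to 5.24% of the counts and stayed in the tests and totals. The 10 most abundant genes held 5.56% to 6.94%. With 16334079 to 19686675 expected counts, 3 counts were worth 0.152 to 0.184 CPM. Intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules.

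Expected counts were rounded to whole numbers and tested in edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr over the 4 groups (minimum count 10) and the quasi-likelihood test. All 12 libraries entered 1 fit with a coefficient per group and no further covariate. The 5 contrasts were differentiation in control cells, differentiation in LIGHT cells, LIGHT against control before and after differentiation, and the interaction. A gene passed with a Benjamini-Hochberg adjusted p under 0.05 over the 12993 genes tested, with no fold threshold. All log2 fold changes are of edgeR unless another tool is named, and CPM are scaled by TMM, given as mean ± SD. Standard errors are the absolute log2 fold change divided by the square root of edgeR's F. For a group at 0 counts the fold is a bound against a floor of 3 counts over the group, and for 1 to 3 counts the ratio has an exact 95% counting interval.

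There were 19 gene lists, namely adipocyte core, thermogenic, oxidative phosphorylation (nuclear genes), tricarboxylic acid cycle and fatty acid oxidation, lipogenesis, PPARγ agonist targets, fibroblast and matrix, signals that oppose adipogenesis, NF-κB, chemokines with cytokines and acute phase, interferon response, LIGHT pathway, cell cycle, p53 and cell death, cholesterol synthesis, leukocytes, muscle with bone and cartilage, endothelial and epithelial cells, and 13 mitochondrially encoded transcripts. Of the last list 0 members were measured, so it is not analysed here. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a contrast, and beside it with an estimated correlation and with fry. The sets of the 200 genes with the largest mean rise and the 200 with the largest mean fall on differentiation were tested in the same way.

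The design, lists, alternatives and the rule for named genes were set before the data were examined. The rule names, for each contrast, Tnfsf14, Ltbr, Tnfrsf14, Pparg, Adipoq, Fabp4, Ucp1, Cidea and Ppargc1a. It adds the 4 largest rises and 4 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the 2 groups (no such condition for the interaction), leaving out predicted genes by the form of their symbol. It also adds up to 3 members with the smallest p of each list described. Some genes that the rule picks are not reported here. Which lists have members named was settled after the list results were seen. Cpt1a was named because it was the only member of its list to go the other way, Lyz2 and Rn28s1 because they mark another cell type and RNA composition, and Dcn, Lum and Pdgfra fall under the rule in the repeat without the 2 libraries.

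The alternatives were DESeq2 1.42.0, RLE scaling, library totals, no low-count filter, a stricter filter (10 counts in every library of a group), a fit of the 2 groups compared, the replicate number as a term, a log2 fold change of at least 1, limma on log2(FPKM + 1) and log2(FPKM + 0.1), sets of 100 and 500 genes, and leaving out each library in turn. Leaving out the 2 differentiated libraries whose Tnfsf14 counts go against their labels, also with DESeq2, library totals and RLE, and for the LIGHT pathway list with Tnfsf14 left out of it, was added after the data were seen, with 13150 genes tested. No library was moved to another group.

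The tests were checked on simulated counts with planted changes in each comparison except differentiation in LIGHT cells. For LIGHT before differentiation, over 12744 genes, edgeR recovered 50% of 1.5-fold, 90.9% of 2-fold and 100% of 4-fold changes, and 5.4% of its calls were not planted. For LIGHT after differentiation the shares were 60.6%, 89.4% and 100% over 12746 genes with 12 libraries, and 86.2%, 90.8% and 100% over 12804 genes without the 2 libraries. The simulated groups shared 1 dispersion and held no library that goes against its label. The shares with 12 libraries are therefore not the power of labelled comparisons that use the 2 libraries whose Tnfsf14 counts go against their labels. For the interaction, over 12743 genes, they were 20.9%, 64.2% and 95.4%, and for differentiation in control cells, over 12763 genes, 56.7%, 90.9% and 100%. Camera called the planted set and 0 of 10 random sets in each comparison simulated. The genes were simulated independently, so this check cannot show how often camera calls a list whose genes are correlated.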

Results

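RNA of 3T3-L1 cells, a mouse line of fibroblast-like preadipocytes that fills with lipid under adipogenic hormones, was sequenced from 4 groups of 3 libraries. A control line and a line that overexpresses LIGHT, the tumour necrosis factor family cytokine encoded by Tnfsf14, were each sampled before and after culture with a cocktail for beige differentiation. Beige adipocytes are fat cells that can carry a thermogenic program. The comparisons address what differed between the stages in each line, how the lines differed at each stage, and whether that difference depended on the stage. Each library held between 16334079 and 19686675 expected counts over 14812 to 15017 listed genes, and 3 counts, the floor used here, were worth 0.152 to 0.184 CPM, the unit of counts scaled to library size. The labels do not state that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples.

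The overexpressed gene was read first in every library. Tnfsf14 (gene 50930) gave 0, 1 and 0 counts in the undifferentiated control libraries and 38, 53 and 58 counts in the undifferentiated LIGHT libraries, which is 2.71 ± 0.438 CPM (SD, n = 3). The ratio of the summed counts was 143, with a 95% counting interval from 25.2 to 5670. In the differentiated LIGHT libraries labelled replicate 2 and 3 the counts were 148 and 122, and in the differentiated control libraries labelled replicate 2 and 3 both were 0. The library labelled differentiated control 1 held 113 Tnfsf14 counts (7.03 CPM), and the library labelled differentiated LIGHT 1 held 0. Both go against their labels. In edgeR's test over all 12 libraries the log2 fold change of Tnfsf14 was 6.69 (SE 2.52, adjusted p = 0.0687) before differentiation and 1.14 (SE 1.28, adjusted p = 0.913) after it. In a fit of the 6 undifferentiated libraries alone it was 6.72 (adjusted p = 2.57e-07).

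**Figure D1:**
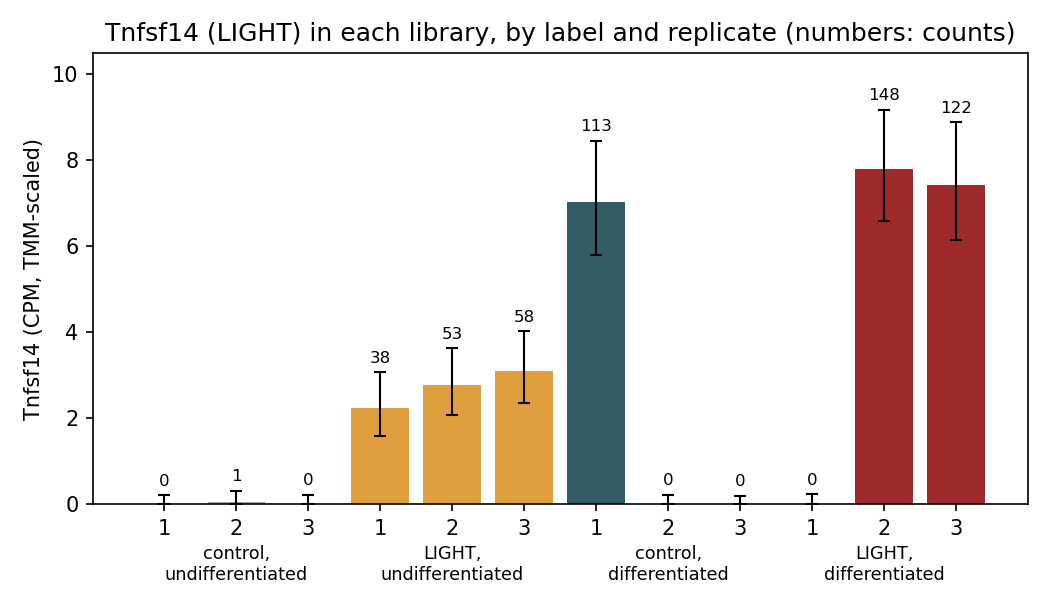
Bars give Tnfsf14 in CPM scaled by TMM for each of the 12 libraries, ordered by label and replicate number. Error bars are 95% Poisson intervals of the count, and the number over each bar is that count. Among the differentiated libraries the count was 113 in control replicate 1 and 0 in LIGHT replicate 1, against 0 in the other control libraries and 148 and 122 in the other LIGHT libraries.

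The same pair stood apart across the transcriptome. The first principal component of log2 CPM held 75.2% of the variance and parted the stages. The second held 9.1% and parted the undifferentiated lines, with control libraries from 23.9 to 27.3 and LIGHT libraries from -27.2 to -23.9. On it the library labelled differentiated control 1 lay at -22.6, beside differentiated LIGHT 2 and 3 at -22.3 and -19.4, and the library labelled differentiated LIGHT 1 lay at 21.2, beside differentiated control 2 and 3 at 21.9 and 19.4. Counts of these libraries differed from those of their own group with a chi-square per gene of 36.2 to 50.4, against 4.2 and 3.55 between replicates 2 and 3 and 2.52 to 7.46 within the undifferentiated groups. Samples were kept in the groups their labels give. Comparisons that use these 2 libraries are reported as labelled. A repeat without them, chosen after the data were seen, is given in full for the lines after differentiation, for the main values of the interaction and the stage sets, and for differentiation only as counts of genes unless stated.

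**Figure D2:**
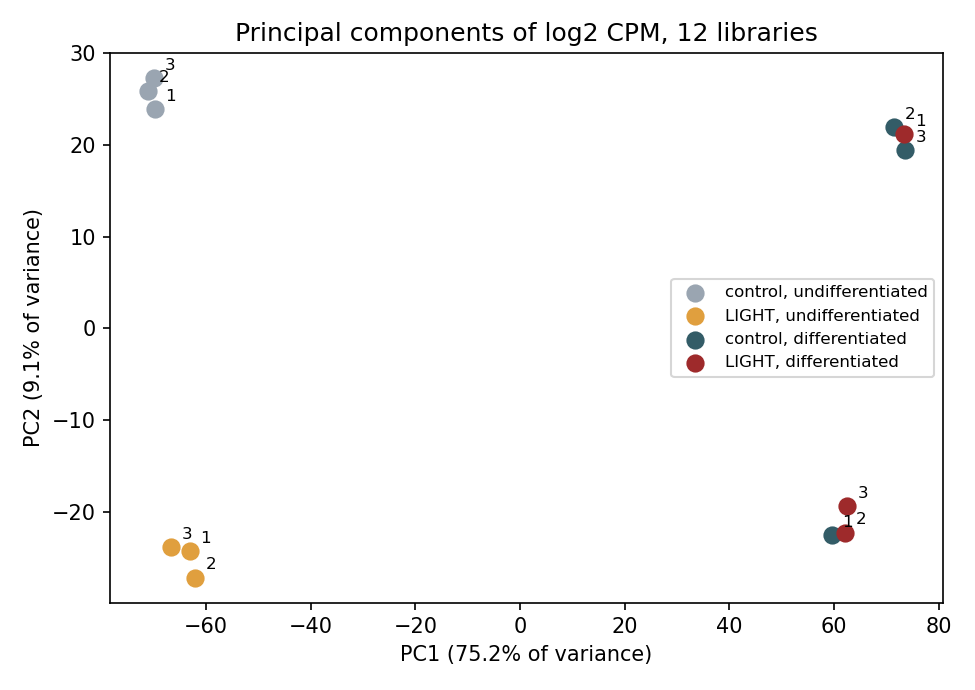
Each point is 1 of the 12 libraries on the first (x) and second (y) principal component of log2 CPM, in arbitrary units, coloured by labelled group. The differentiated control library labelled 1 lies at -22.6 on the second component and the differentiated LIGHT library labelled 1 at 21.2, each beside libraries of the other line.

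In differentiated control cells genes of the adipocyte program, oxidative metabolism and lipid synthesis were higher than before differentiation, and cell cycle and interferon genes lower. The day of harvest is not given, so an effect of the cocktail cannot be told apart from time in culture or the maintenance medium. All 21 measured genes of the adipocyte core list rose, also when adjusted over the list alone. Adipoq, the hormone adiponectin (gene 11450), went from 2.51 ± 0.508 to 1270 ± 188 CPM (SD, n = 3), a log2 fold change of 8.98 (SE 0.31, adjusted p = 1.57e-10, edgeR). Fabp4, a fatty acid carrier, went from 27.5 ± 2.44 to 9970 ± 2600 CPM (log2 fold change 8.5), and Pparg, the nuclear receptor that drives adipogenesis, from 12.4 ± 0.588 to 114 ± 21.1 CPM (3.2). Acsl1, Pnpla2 and Cebpa had the smallest p-values of the list, with log2 fold changes of 5.96, 6.05 and 5.48. Of 14 measured thermogenic genes 13 rose and 0 fell, the same 13 in number when adjusted over the list alone. Among them were Kcnk3 (4.28), Ebf2 (2.6) and Slc36a2, which was at least 71.6-fold higher than a floor of 3 counts over the undifferentiated group, and Ppargc1a, a coactivator of mitochondrial biogenesis, rose by 2.09 in log2 (SE 0.3). Ucp1, the uncoupling protein of thermogenic fat, had 0 to 2 counts per library and Cidea 0 to 6 in all 12 libraries, so neither was tested and no fold is given. Prdm16, Dio2, Tmem26, Tnfrsf9 and Ckb of the thermogenic list and Lep of the core list did not pass the low-count filter either. Gyk, Tbx1, Zic1, Gatm and Ckmt2 of the thermogenic list were listed in no library. The 14 and the 21 leave all of these out. Slc36a2 and Elovl3, with 0 counts in every undifferentiated library, passed the filter only through the differentiated libraries and could only rise. Cox7a1 and Cited1, and Cfd and Slc2a4 of the core list, had at most 6 counts in any undifferentiated library of either line. They too passed only through the differentiated libraries, so the counts of genes that rose are partly fixed by the filter.

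All 39 measured nuclear genes of oxidative phosphorylation rose in differentiated control cells, among them Uqcrh (log2 fold change 2.06), Cox7b (1.45) and Atp5j (0.88). Of 30 genes of the tricarboxylic acid cycle and fatty acid oxidation 29 rose, led by Acadm (3.51), Acads (2.17) and Hadh (1.99), and 1, the carnitine palmitoyltransferase Cpt1a, fell (-0.38). Of 20 lipogenic genes 19 rose and 0 fell. Thrsp went from 0.0763 ± 0.0661 to 70.1 ± 9.81 CPM, Pcx from 39.5 ± 2.57 to 1580 ± 101 and Dgat2 from 8.69 ± 0.423 to 142 ± 5.08. Targets of the PPARγ agonist class rose in 11 of 13, 12 when adjusted over the list alone. Of 19 cholesterol synthesis genes 15 rose and 0 fell, including Insig1 (2.81), Mvd (2.15) and Nsdhl (1.27). The camera adjusted p of these 6 lists and the core list lay between 6.28e-15 and 8.19e-06. With an estimated correlation adjusted p ranged from 0.0547 for lipogenesis and 0.0563 for the adipocyte and thermogenic lists to 0.108 for the agonist targets and 0.249 for the other 3, so none of the calls held.

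Of 30 cell cycle genes 30 fell in control cells, with Ccnd1 from 610 ± 20.6 to 111 ± 14.5 CPM, Bub1b from 175 ± 5.84 to 54.2 ± 2.1 and Bub1 from 78.9 ± 6.41 to 24.8 ± 0.242. Of 30 interferon response genes 26 fell and 0 rose, including Oas1a (-3.61), Irgm1 (-2.59) and Bst2 (-2). Of 23 chemokine, cytokine and acute phase genes 16 fell and 4 rose. Cxcl5 (-5.05) and Ccl5 (-3.03) fell, and the acute phase gene Hp rose by 5.54. Camera gave adjusted p = 6.28e-14, 2.43e-07 and 0.00304 for these 3 lists, and 0.0547, 0.298 and 0.249 with an estimated correlation. Counts adjusted over each list alone were the same. Fibroblast and matrix genes went both ways, 11 up and 10 down of 26 (camera adjusted p = 0.75), with Col6a1 (2.29) and Col6a2 (2.74) up and the contractile gene Tagln (-3.3) down. Of 18 signals that oppose adipogenesis 8 fell and 4 rose (0.215), with Ctgf at -6.4, Inhba at -3.26 and Foxc2 at -1.28. The regulators and targets of NF-κB (6 up, 4 down of 19, 3 down when adjusted over the list alone, 0.75), the LIGHT pathway (3 up, 3 down of 12, 2 up when adjusted over the list alone, 0.813) and the p53 and cell death list (6 up, 8 down of 18, 0.538) were not called. Ltbr, a receptor of LIGHT, did not pass the test (0.23, adjusted p = 0.131), and Tnfrsf14, the other receptor, rose by 1.85 (adjusted p = 0.0112), a call lost without undifferentiated control 2 (0.0506). The Tnfsf14 ratio of 116 (95% counting interval 20.3 to 4610; adjusted p = 0.0431) rests on the library labelled differentiated control 1, without which 0 counts stood against 1.

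The largest rises in control cells that met the level and separation conditions were those of the transaminase Gpt, the fatty acid receptor Ffar2, the transporter Slc13a4 and the protease inhibitor Timp4. Gpt was at least 907-fold, Ffar2 at least 248-fold and Slc13a4 at least 190-fold higher than a floor of 3 counts over the group, and the Timp4 ratio was 2050 (95% counting interval 368 to 81100). The largest falls were those of Il1rl1, the receptor of interleukin 33, from 121 ± 8.62 to 0.845 ± 0.259 CPM (-7.16, SE 0.18), Il18rap (-6.86), Siglecg (-6.79) and Itgb7 (-6.68). Chance separates 3 libraries from 3 in 10% of genes. In all, 8307 of 12993 tested genes passed the threshold in edgeR's quasi-likelihood test, 4186 up and 4121 down, and 9292 without the 2 doubted libraries. With library totals in place of TMM the median log2 fold change of all genes was -0.113 instead of 0. Without the 2 libraries it was -0.147 instead of 0.01, and library totals gave 40.1% of calls higher instead of 50.6%. Among markers of other cell types, 0 of 5 leukocyte genes rose and 3 fell (camera adjusted p = 0.0538), 2 of 7 muscle, bone and cartilage genes rose and 3 fell (0.869), and 4 of 5 endothelial and epithelial genes rose and 1 fell (0.346). The counts of these 3 lists were the same when adjusted over the list alone.

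In the LIGHT line the adipocyte, oxidative and lipogenic lists were higher after differentiation, and cell cycle and interferon genes lower. Adipoq went from 1.83 ± 0.979 to 1140 ± 251 CPM (log2 fold change 9.29, SE 0.31, adjusted p = 1.77e-10, edgeR), Fabp4 from 17.4 ± 7.84 to 8700 ± 2550 (8.97), Pparg from 7.46 ± 0.349 to 104 ± 11.7 (3.8) and Ppargc1a from 1.14 ± 0.312 to 9.77 ± 2.02 (3.09). All 21 adipocyte core genes and all 39 oxidative phosphorylation genes rose, as did 29 of 30 genes of the tricarboxylic acid cycle and fatty acid oxidation, 17 of 20 lipogenic genes with 3 falling, 12 of 14 thermogenic genes and 10 of 13 agonist targets. Kcnk3 rose by 3.35 and Ebf2 by 3.67, and the lipogenic genes Thrsp, Pcx and Dgat2 by 8.46, 4.96 and 4.38. Of 30 interferon genes 29 fell, and of 30 cell cycle genes 28 fell and 0 rose, 2 rising when adjusted over the list alone. The p53 and cell death list fell in 11 of 18 and rose in 5 (camera adjusted p = 0.0386), with Ccng1 (-1.03) and Mlkl (-0.92). Its adjusted p was 0.106 with an estimated correlation and 0.0595 without the 2 doubted libraries. For the other lists called, adjusted p with an estimated correlation lay between 0.0551 and 0.247. Cholesterol synthesis rose in 10 of 19 and fell in 4, a list not called (0.0739), with Insig1 (2.08), Pmvk (1.68) and Dhcr7 (1.52) up.

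Lists not called in the LIGHT line were chemokines and cytokines (5 up, 12 down of 23, camera adjusted p = 0.0903), fibroblast and matrix genes (10 up, 10 down of 26, 11 up when adjusted over the list alone, 0.923), signals that oppose adipogenesis (3 up, 9 down of 18, 0.0955), NF-κB (4 up, 4 down of 19, 3 down when adjusted over the list alone, 0.999) and the LIGHT pathway (1 up, 1 down of 12, 0.559). The leukocyte list had 1 up and 3 down of 5 (0.192), muscle, bone and cartilage 3 up and 3 down of 7 (0.968; 4 up when adjusted over the list alone), and endothelial and epithelial genes 4 up and 1 down of 5 (0.194). Counts adjusted over the list alone were otherwise the same. Ltbr (0.23, adjusted p = 0.131) and Tnfrsf14 (-0.29, 0.635) did not pass the test. Ltbr was at 126 CPM in the library labelled differentiated LIGHT 1 and at 171 and 174 CPM in LIGHT 2 and 3. The undifferentiated LIGHT libraries were at 131, 131 and 139 CPM. Among the largest rises were Olr1, a receptor of oxidised low-density lipoprotein, at least 401-fold higher, Slc2a4, the insulin-responsive glucose transporter, with a ratio of 3220 (95% counting interval 578 to 127000), and Cfd, with 1740 (480 to 14300). The largest falls were Ankrd1 (-6.07), Siglecg (-5.49), Usp17le (-5.47) and Cxcl5 (-5.13). In all 7612 genes passed, 3835 up and 3777 down, and 8432 without the 2 doubted libraries. Across genes the changes of the lines correlated with r = 0.886, where genes are not independent replicates. Both comparisons called 6325 genes, 3197 up in both and 3043 down in both, against 1236 and 1198 for independent lists. Each differentiated group as labelled holds 1 of the 2 doubted libraries. Without them r was 0.858 and 7074 genes were called in both comparisons. Of these 6784 changed in the same direction, against 6240 of the 6325 as labelled.

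Before differentiation the LIGHT line differed from control in Fos and Fosb and in cholesterol synthesis, cell cycle and interferon genes. Fos, a component of the transcription factor AP-1, was at 2.28 ± 0.14 CPM in control and 26.7 ± 6.67 in LIGHT libraries (SD, n = 3), a log2 fold change of 3.55 (SE 0.21, adjusted p = 1.19e-06, edgeR), and Fosb was higher by 3.6 (SE 0.33). Of 19 cholesterol synthesis genes 16 were higher and 0 lower. Mvd went from 49.9 ± 2.36 to 105 ± 1.53 CPM, Nsdhl from 64.4 ± 1.69 to 98.3 ± 3.45, and Srebf2, the transcription factor of the pathway, from 227 ± 6.83 to 337 ± 19.2. Of 30 cell cycle genes 18 were lower and 0 higher, 23 lower when adjusted over the list alone, with Rrm2 at -0.81, Ccnd1 at -0.71 and Bub1 at -0.48. Of 30 interferon response genes 13 were higher and 0 lower, 14 when adjusted over the list alone, among them the immunoproteasome subunits Psmb9 (1.26) and Psmb8 (0.8) and Ifi44 (1.05). The p53 and cell death list had 7 of 18 higher and 2 lower, 8 higher when adjusted over the list alone, with Trp53inp1 (0.85), Bbc3 (0.75) and Sesn2 (0.46). Camera gave adjusted p = 2.9e-09, 4.73e-09, 0.000182 and 0.0235 for these 4 lists, and 0.287, 0.167, 0.815 and 0.167 with an estimated correlation. The interferon call was lost with fry (0.107). The p53 call was also lost without undifferentiated control 1 (0.0506).

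Adipocyte regulators of the undifferentiated LIGHT cells moved apart. Pparg was lower (7.46 ± 0.349 against 12.4 ± 0.588 CPM, -0.73, adjusted p = 0.00368, edgeR) while Cebpa (0.75) and Pnpla2 (0.42) were higher, and of 21 adipocyte core genes 4 were higher and 1 lower (camera adjusted p = 0.737). Adipoq (-0.46), Fabp4 (-0.66), Ppargc1a (-0.72) and Ltbr (0.23) had adjusted p of 0.396, 0.153, 0.14 and 0.191, and Tnfrsf14 was higher by 1.65 (0.0473). That call was lost without any 1 of undifferentiated control 1 (0.158) or 2 (0.161) or LIGHT 1 (0.0725), 2 (0.159) or 3 (0.0784), and with no low-count filter (0.0596). Collagens Col3a1 (1.09), Col6a1 (0.96) and Col6a2 (1.16) were higher among 9 fibroblast and matrix genes higher and 4 lower of 26 (0.21). Of 23 chemokine and acute phase genes 5 were lower and 3 higher (0.247), with Lcn2 from 18.2 ± 1.64 to 2.6 ± 0.74 CPM, Mmp3 from 42 ± 3.78 to 6.77 ± 0.8 and Cxcl1 higher by 1.03, and 6 were lower when adjusted over the list alone. Of 18 signals that oppose adipogenesis 3 were higher and 3 lower (0.82), with Ctgf (-2.08) lower and the preadipocyte gene Dlk1 (0.61) higher. Of 20 lipogenic genes 8 were higher, 9 when adjusted over the list alone, and 3 lower (0.101), with Fads2 (0.7), Fads1 (0.42) and Acacb (0.6) higher. NF-κB genes were 2 higher and 1 lower of 19 (0.21), with Bcl3 (0.92) and Nfkbiz (0.58) higher and Tnip3 (-3.39) lower, and the Nfkbiz call was lost without undifferentiated control 2 (0.0516) or 3 (0.0538). The thermogenic list (0 higher, 1 lower of 14, 0 lower when adjusted over the list alone, 0.859), oxidative phosphorylation (3 higher, 0 lower of 39, 0.617), the tricarboxylic acid cycle and fatty acid oxidation (4 higher, 2 lower of 30, 0.617), agonist targets (1 higher, 2 lower of 13, 0.617) and the LIGHT pathway (2 higher, 1 lower of 12, 0.398) were not called. Counts adjusted over the list alone were otherwise the same.

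The other largest differences before differentiation were Frmpd4, from 0.115 ± 0.0586 to 25.9 ± 0.635 CPM (log2 fold change 7.73, SE 1.88, adjusted p = 0.00999, edgeR), and Akr1c12 (3.72) among genes higher in LIGHT cells, and U90926 (-3.64), Stac2 (-3.2), the phosphatase Dusp3 (-3) and the 18S ribosomal RNA gene Rn18s (-2.97) among genes lower. Rn18s lost its call without undifferentiated control 2 (0.139) or 3 (0.0803) or LIGHT 1 (0.107), 2 (0.0503) or 3 (0.105), and with DESeq2 (0.107, and 0.143 without the 2 doubted libraries). The ribosomal RNA gene Rn28s1 was lower as well (adjusted p = 0.000651, edgeR), at 33.4, 25.7 and 22.2 CPM in control and 10.8, 11.9 and 13.7 in LIGHT libraries. Of 5 leukocyte markers 3 were lower and 1 higher (camera adjusted p = 0.21), with Lyz2 at 2.25, 1.97 and 2.04 CPM against 0.591, 0.524 and 0.268. Muscle, bone and cartilage markers were 1 higher and 2 lower of 7 (0.617), and endothelial and epithelial markers 0 and 0 of 5 (0.644). In all 3446 genes passed, 1604 higher and 1842 lower, of which 487 changed by a log2 of at least 1. The 2 doubted libraries are not part of this comparison but of its shared estimate of the spread. Without them 5836 genes passed, 2935 higher and 2901 lower, and 3445 of the 3446 were among them in the same direction. Without undifferentiated LIGHT 2 the count was 2238.

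After differentiation, with libraries grouped as labelled, 0 of 12993 genes passed edgeR's test between the lines, 523 had an unadjusted p under 0.05, and DESeq2 called 1 gene, the ribosomal RNA gene Rn28s1 (log2 fold change 0.98, SE 0.2, adjusted p = 0.0149), named after its value was seen. Adipoq (-0.15, adjusted p = 0.92), Fabp4 (-0.2, 0.924), Pparg (-0.13, 0.913), Ppargc1a (0.29, 0.913), Ltbr (0.24, 0.913) and Tnfrsf14 (-0.5, 0.913) did not pass. No member of any list passed over all genes or adjusted over the list alone. Camera placed oxidative phosphorylation (adjusted p = 0.0122, median log2 fold change -0.07), the tricarboxylic acid cycle and fatty acid oxidation (0.0113, -0.11) and cholesterol synthesis (0.0277, -0.11) lower in LIGHT libraries. With an estimated correlation adjusted p was 0.945 for each, and each call was lost without any 1 of differentiated control 2 or 3 or LIGHT 2 or 3, the lowest adjusted p of those fits being 0.135, 0.0782 and 0.135. For the other 15 lists tested adjusted p lay between 0.295 and 0.953.

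Without the 2 doubted libraries, a comparison of 2 against 2 chosen after the data were seen, genes of NF-κB and chemokine signalling were higher and mitochondrial genes lower in the libraries labelled LIGHT. Nfkb2, the subunit of the noncanonical NF-κB pathway that receptors of this family engage, went from a mean of 90.6 to 183 CPM (log2 fold change 1, SE 0.07, adjusted p = 9.25e-09, edgeR, n = 2), Nfkbie from 3.48 to 15.3 CPM (2.13) and Vcam1 from 46.5 to 95.7 CPM (1.04). Of 19 genes of the list 9 were higher and 2 lower. Of 22 chemokine, cytokine and acute phase genes 10 were higher and 3 lower, 11 and 4 when adjusted over the list alone, with Cxcl12 from 372 to 756 CPM, the macrophage growth factor Csf1 from 75.5 to 134 and complement C3 from 887 to 1490. Of 12 LIGHT pathway genes 6 were higher and 1 lower, 8 and 2 when adjusted over the list alone, with Traf2 (0.81) and Ltbr (0.51). The count includes Tnfsf14, at 270 against 0 counts, a difference fixed by the choice of the libraries left out. With Tnfsf14 left out of the list 5 of 11 genes were higher and 1 lower, 7 and 2 when adjusted over the list alone, with a camera adjusted p of 0.0183, and 0.228 with an estimated correlation. Of 30 interferon response genes 10 were higher and 1 lower, 13 higher when adjusted over the list alone, with B2m (0.61), H2-K1 (0.54) and H2-D1 (0.35), the chains of class I antigen presentation. Camera gave adjusted p = 0.00237 for each of these 4 lists, and with an estimated correlation 0.0777 for the first 3 and 0.389 for the interferon list.

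Of 39 oxidative phosphorylation genes 34 were lower and 0 higher in this repeat, with Ndufs1 from 229 to 156 CPM, Uqcrfs1 from 421 to 301 and Ndufb9 from 275 to 206. Of 30 genes of the tricarboxylic acid cycle and fatty acid oxidation 23 were lower, 24 when adjusted over the list alone, and 1, Cpt1a, higher (0.21), with Etfa (-0.55) and Idh3a (-0.51) lower. Of 19 cholesterol synthesis genes 15 were lower and 0 higher, 1 higher when adjusted over the list alone, with Lss (-0.61), Hmgcs1 (-0.51) and Sqle (-0.43). Agonist targets were lower in 8 of 13 and higher in 1, with Hilpda (-0.82) and Angptl4 (-0.47) lower. Cell cycle genes were higher in 11 of 30, 12 when adjusted over the list alone, and lower in 1, with Mcm4 (0.67), Mcm5 (0.4) and Mcm6 (0.3) higher. Camera adjusted p was 3.55e-10, 1.53e-07, 8.01e-05, 0.0217 and 0.0086, and with an estimated correlation 0.322, 0.322, 0.228, 0.322 and 0.322. Single adipocyte genes were lower in a list that was not called. Adipoq was at 1370 CPM in control and 999 CPM in LIGHT libraries (-0.47, adjusted p = 0.00101), Fabp4 at 11500 and 7230 (-0.67), Pparg at 126 and 97.7 (-0.37) and the glucose transporter Slc2a4 at 83.7 and 44.4 (-0.92). Of 21 core genes 9 were lower and 1 higher, 2 higher when adjusted over the list alone (camera adjusted p = 0.118), and of 14 thermogenic genes 5 were lower and 1 higher (0.118), with Cox7a1 (-1.74), Ebf2 (-0.71) and Kcnk3 (-0.68) lower and Ppargc1a (0.76) higher. Cfd (-0.65) and Lpin1 (-0.45) were lower.

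**Figure D3:**
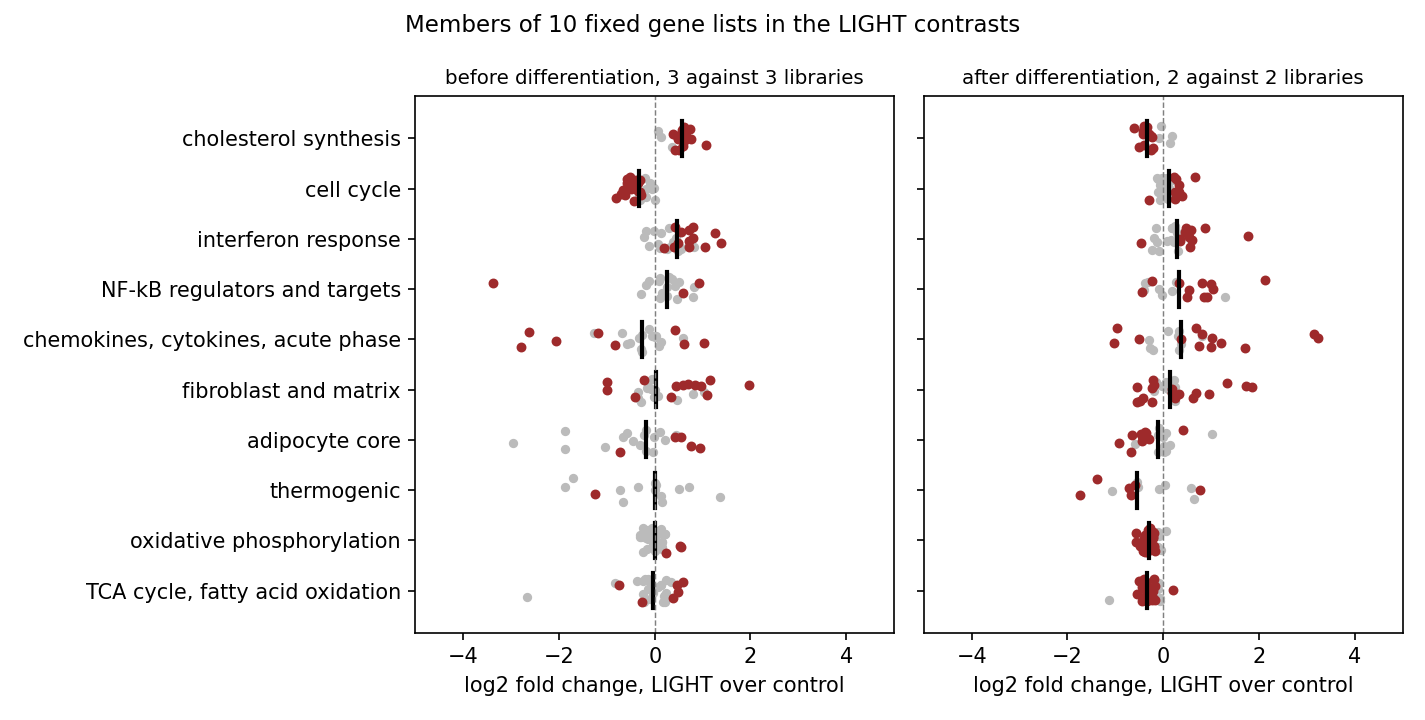
Each point is a member of 1 of 10 gene lists, placed by its log2 fold change of LIGHT over control, before differentiation on the left (3 against 3 libraries) and after it on the right (2 against 2, without the 2 doubted libraries). Red points passed the threshold, grey points did not, and black bars are medians, which went from 0.57 to -0.34 for cholesterol synthesis, from -0.33 to 0.11 for the cell cycle and from 0.01 to -0.29 for oxidative phosphorylation.

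Single fibroblast and matrix genes differed between the lines in this repeat. Dcn went from 172 to 580 CPM (1.74), Lum from 46.5 to 170 (1.86) and the fibroblast receptor Pdgfra from 96.8 to 246 (1.34), within a list of 26 of which 10 were higher and 8 lower, 11 and 9 when adjusted over the list alone (camera adjusted p = 0.17). Frmpd4 gave a ratio of 469 (95% counting interval 83.7 to 18600), and Peg3 (-2.91), Crip1 (-3.23) and Adgrf5 (-2.74) were lower. Tmem254b (6.75) and Tmem254c (-5.16) are near-identical copies whose reads the counting could split, so their opposite changes are uncertain. Lists not called were lipogenesis (2 higher, 8 lower of 20, 0.0617), p53 and cell death (3 higher, 6 lower of 18, 7 lower when adjusted over the list alone, 0.405), signals that oppose adipogenesis (5 higher, 5 lower of 19, 0.782), leukocytes (1 higher, 0 lower of 6, 0.612), muscle, bone and cartilage (2 higher, 1 lower of 7, 0.612) and endothelial and epithelial genes (0 higher, 3 lower of 6, 0.118). Counts adjusted over the list alone were otherwise the same. In all 4079 of 13150 genes passed, 1922 higher and 2157 lower, 458 of them by a log2 of at least 1. Scaled to library totals 66% of the calls were higher instead of 47.1%, oxidative phosphorylation was lower in 23 of 39, the tricarboxylic acid cycle and fatty acid oxidation in 17 of 30, cholesterol synthesis in 10 of 19 with 2 higher, and the medians of the p53 and anti-adipogenic lists changed sign (to 0.01 and 0.02).

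**Figure D4:**
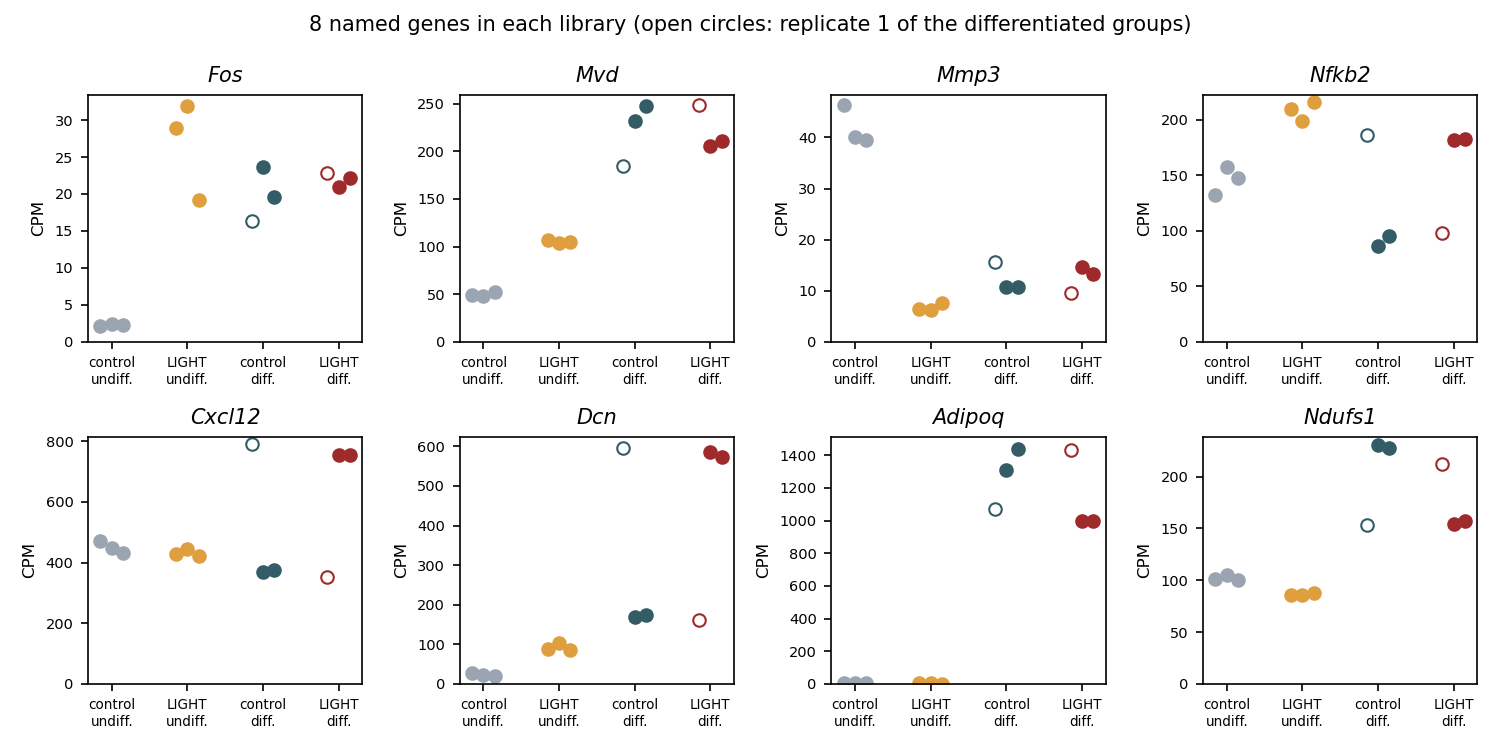
CPM of Fos, Mvd, Mmp3, Nfkb2, Cxcl12, Dcn, Adipoq and Ndufs1 in each of the 12 libraries, by labelled group, with open circles for replicate 1 of the differentiated groups. Mvd had a mean of 49.9 CPM in undifferentiated control and 105 in undifferentiated LIGHT libraries, and for Nfkb2, Cxcl12, Dcn and Ndufs1 each open circle lies nearer to the libraries of the other label than to its own.

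Whether the difference between the lines, called the LIGHT effect here, depended on the stage was tested as an interaction. With 1 line of each kind, an effect of LIGHT cannot be told apart from other differences between the lines. As labelled, 1214 genes passed, 660 with an effect more positive after differentiation and 554 more negative, and 1206 of them also passed without the 2 doubted libraries, in the same direction, among 4077 (1964 and 2113, or 2771 and 1469 scaled to library totals). Fos (-3.4, SE 0.27), Fosb (-3.56), the transcription factor Egr1 (-2.58) and Gap43 (-2.63) had the most negative interactions, and Olr1 (6.7), Rn18s (5.49), U90926 (4.06) and Itgb7 (3.74) the most positive. The Olr1 value is not a measured fold, since undifferentiated LIGHT cells had 0 counts, and its call was lost with limma on log2(FPKM + 1), at 0.42 (adjusted p = 0.216). In the repeat these were -3.57, -3.85, -2.43, -3.15, 6.96, 4.6, 4.71 and 3.39. The Rn18s and U90926 calls of the labelled fit were lost without single libraries, at adjusted p of up to 0.0736 for Rn18s (undifferentiated control 2) and up to 0.26 for U90926 (differentiated LIGHT 2). Rn18s was also lost with DESeq2 (0.0512, and 0.176 in the repeat), and U90926 with limma on log2(FPKM + 0.1) (0.0687). Of 19 cholesterol synthesis genes 13 had a more negative effect after differentiation, 18 when adjusted over the list alone and 19 in the repeat, with Mvd at -1.07, Nsdhl at -0.62 and Msmo1 at -0.85. Of 30 cell cycle genes 14 had a more positive one, 17 when adjusted over the list alone and 25 in the repeat, with Rrm2 (0.75), Ccnd1 (0.78) and Mcm7 (0.52). Camera adjusted p was 6.38e-12 and 2.28e-10, and 0.174 and 0.141 with an estimated correlation, or 0.0524 and 0.0531 in the repeat. Interferon (0 positive, 6 negative of 30, 5.1e-05; 0.717 with an estimated correlation), p53 (0 and 4 of 18, 8 negative when adjusted over the list alone, 0.0214; 0.141) and lipogenesis (1 and 4 of 20, 2 and 7 when adjusted over the list alone, 0.0364; 0.524) were called as labelled, and the interferon call was lost in the repeat (0.252) and with fry (0.186). The lipogenesis call was lost with fry (0.0653) and without any 1 of undifferentiated LIGHT 1 (0.0534) or control 2 (0.0834), or differentiated LIGHT 2 (0.0929) or 3 (0.0508) or control 3 (0.0958).

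In the repeat the interaction also called oxidative phosphorylation (0 positive, 27 negative of 39, 30 when adjusted over the list alone, camera adjusted p = 1.27e-08), with Cox7b (-0.75), Ndufv2 (-0.57) and Uqcrc2 (-0.54), the tricarboxylic acid cycle and fatty acid oxidation (1 positive, 19 negative of 30, 21 negative when adjusted over the list alone, 1.67e-05), with Etfa (-0.9), and the chemokine and cytokine list (11 positive, 2 negative of 22, 0.000526), with Csf1 (1.65), Cxcl12 (1.07) and Mmp3 (2.99). With an estimated correlation adjusted p was 0.332, 0.343 and 0.0524. The desaturases Scd1 (-1.18) and Scd2 (-1.07) had more negative effects after differentiation, as did Gadd45a (-1.4) and Cdkn1a (-0.83). Ppargc1a (1.47), Pparg (0.35) and Ltbr (0.26) had more positive ones, and Adipoq (-0.01, adjusted p = 0.99, edgeR) and Fabp4 (-0.02, 0.972) did not pass.

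The genes that changed most on differentiation were then read in the comparisons of the lines, in sets of 200 with the largest mean rise and fall over both lines. Before differentiation the set that falls was lower in LIGHT cells, with a median log2 fold change of -0.238, 47 members lower and 11 higher (camera adjusted p = 0.0191; 0.0708 with an estimated correlation), and the set that rises had 8 members higher and 6 lower (0.945). After it, as labelled, neither set was called (adjusted p = 0.489 and 0.668). Without the 2 doubted libraries the set that rises had a median of -0.228, 62 members lower and 18 higher (0.0142; 0.382 with an estimated correlation), and the set that falls had 18 lower and 21 higher (0.515). In the interaction the set that falls was positive as labelled (median 0.147, 16 members positive and 1 negative, 0.029; 0.0886 with an estimated correlation), and the set that rises was not called (0.603). The call was lost with sets of 500 genes (0.129) and with library totals (0.0998), and the median was -0.17 without differentiated LIGHT 1 and 0.604 without differentiated control 1. In the repeat the set that falls had 24 members positive and 10 negative (0.0217; 0.0377 with an estimated correlation), and the set that rises 7 positive and 21 negative (0.069).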

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

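The tests of exchanged labels, of a mixture of the lines, of no difference between the lines, of a single library behind the immediate early genes and of the scaling, and all fits without the 2 doubted libraries, were chosen only after the result was seen.

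The test of the interaction picked out genes whose LIGHT effect differed between the stages, 1214 as labelled and 4077 without the 2 doubted libraries. Among single genes it picked out Egr1 (-2.58), Fos (-3.4), Fosb (-3.56), Gap43 (-2.63), Itgb7 (3.74), Olr1 (6.7), Rn18s (5.49) and U90926 (4.06), in log2. The Olr1 value rests on a group at 0 counts and is not a measured fold. Of 100 splits of the libraries 7, the labelled one included, gave at least 1214 genes, so this test does not exclude chance for the count as labelled. The other 6 all kept the undifferentiated groups whole, so they still hold the difference between the undifferentiated lines and are not purely chance splits. The highest, with 5999 genes, parted the differentiated libraries as an exchange of replicate 1 would, but set against the opposite undifferentiated line, and a count several times the labelled one points to a structure of the samples.

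As labelled, no gene passed between the lines after differentiation in edgeR's test, where 523 had an unadjusted p under 0.05 and DESeq2 called 1. The other 4 differentiated libraries gave 4079 genes in their labelled split and 0 and 0 in the other 2 splits of those 4. This goes against an absence of any difference by label among these 4 libraries. They were kept by their Tnfsf14 counts after the data were seen, and 3 splits are too few for a share under 0.05. The splits therefore do not exclude chance. A near-even mixture of both lines in each library is argued against. It was read over 5600 genes called in a fit of the undifferentiated groups alone, Tnfsf14 left out. The scale ran from the mean of differentiated control 2 and 3 (0) to that of LIGHT 2 and 3 (1). On it the library labelled LIGHT 1 lay at 0.126 and the library labelled control 1 at 0.943. The 4 libraries that set the scale lay at -0.038, 0.038, 1.024 and 0.976, around 0 and 1 by construction, and are no independent check. A small share of a second line in either library is not excluded. Exchanged labels of these 2 libraries are a candidate explanation, since the difference control 1 minus LIGHT 1 correlated across the same genes with the LIGHT minus control difference of the other 4 libraries at r = 0.714, against 0.705 between the differences of replicates 2 and 3. The ribosomal RNA gene Rn28s1, the 1 gene that DESeq2 called, instead followed the labels as given. It was at 7.77, 9.93 and 8.1 CPM in differentiated control and 19.9, 13.5 and 17.6 in differentiated LIGHT libraries. It is a single gene picked by that labelled comparison, and it marks RNA composition. Whether any exchange took place stays open, and a biological difference between the cultures of replicate 1 was not tested.

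The immediate early genes Fos and Fosb were among the largest rises in undifferentiated LIGHT cells, a group not tested here as a set. A single library as the source is argued against, since Fos and Egr1 kept an adjusted p of at most 4.1e-05 (edgeR) in each of the 6 fits that leave out 1 undifferentiated library. A general response to handling or serum cannot be told apart from an effect of LIGHT or another difference between the lines. Of 33 measured immediate early genes 14 were higher and 6 lower, between the bounds set for either reading, and the labels give no time of harvest. Fosl1 (-2.15), Myc (-0.51) and Id1 (-0.96) were among the lower ones. Without the 2 doubted libraries 11 were higher and 9 lower after differentiation.

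Without the 2 doubted libraries, oxidative phosphorylation genes were lower in differentiated LIGHT cells, a list call not kept with an estimated correlation (0.322), and 9 of 21 adipocyte core genes were lower and 1 higher in a list not called (0.118). The scaling between libraries as the whole source is argued against, since the median of the oxidative phosphorylation list stayed at -0.21 with library totals and 38 of its 39 members lay below the median of all genes, an order that no scaling of whole libraries changes. A smaller share of differentiated cells cannot be told apart from an effect of LIGHT, or another difference between the lines, within each cell. Of the 200 genes that rise most on differentiation 62 were lower but 18 higher, between the bounds set for either reading. Of the 200 that fall most 21 were higher and 18 lower.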

How the results depend on the processing

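The fits without the 2 doubted libraries (differentiated control 1 and LIGHT 1) were chosen only after the result was seen; the other alternatives were planned. Over all alternatives, named genes kept their side of the threshold in 4612 cases, passed it newly in 382, lost it in 112 and reversed in 5. List tests did so in 1085, 46, 57 and 1. A result called in neither fit counts as kept even where its sign changed, and the direction of a list is that of camera, not of its median. Causes were not tested unless stated.

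A log2 fold change of at least 1 left 3094, 2647, 487, 0 and 223 genes in the order control differentiation, LIGHT differentiation, LIGHT before, LIGHT after and interaction. Without the 2 doubted libraries LIGHT before gave 5836 genes (DESeq2 5431, library totals 5853, RLE 5864) and 5601 in the fit of its 2 groups, LIGHT after 4079 (3694, 4341, 4068; DESeq2 on all libraries 1), and the interaction 4077 (3777, 4240, 4045). Leaving out 1 library gave 7581 to 8538, 6872 to 7290, 2238 (without undifferentiated LIGHT 2) to 2611, 0 to 0, and 675 (undifferentiated LIGHT 2) to 1868 (differentiated control 1) genes, with interaction counts of 735 without undifferentiated LIGHT 1, 768 without undifferentiated control 2 and 791 without control 3.

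Tnfsf14 before differentiation passed with no filter (6.71), its 2 groups alone (6.72) or without the 2 libraries (6.71, DESeq2 7.05, totals 6.7, RLE 6.7), and was 6.25 to 8.57 when 1 library was left out. In that range the fit without undifferentiated control 2 stands on a control group at 0 counts and gives no fold. After differentiation Tnfsf14 passed without the 2 libraries, as their choice by its count fixed. The fitted values of 10.09, 9.49, 10.06 and 10.08 stand on a group at 0 counts, and only a bound of 89.2-fold can be read. With 1 library left out Tnfsf14 was at 0.55 to 9.5, where the fit without differentiated control 1 also stands on a group at 0 counts and gives no fold. Its rise in control cells was absent without the library labelled differentiated control 1 or without both, where fitted values (-1.87; -1.88, -0.95, -1.92, -1.89) stand on 1 count against 0 and give no fold. Without undifferentiated control 1, 2 or 3 it was 6.02, 8.33 and 6.02 and did not pass (adjusted p = 0.111, 0.107 and 0.111), nor did it with limma on log2(FPKM + 1) (0.342) or log2(FPKM + 0.1) (0.361). The value of 8.33 stands on a group at 0 counts and gives no fold.

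Camera called 10, 9, 4, 3 and 5 lists, 0 of each with an estimated correlation; fry called 17, 14 and 0 in control differentiation, LIGHT differentiation and LIGHT after. Without the 2 libraries LIGHT after had 9, and the interferon median reversed to 0.29. Leaving out 1 library gave 10 to 10, 9 to 11, 3 to 4, 0 (LIGHT 2 or 3) to 6 (LIGHT 1), with 1 without control 3, and 4 to 8 (differentiated control 1 or LIGHT 1).

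Among the sets of stage genes, the falling set before differentiation was -0.164 with 500 genes (adjusted p = 0.063) and -0.365 to -0.273 with 1 library left out. In LIGHT after, the rising set was -0.216 without differentiated control 1 and -0.228 without both libraries (range -0.216 to -0.022), and the falling set reversed to 0.273 without differentiated control 1 (range -0.137 to 0.273). In the interaction the falling set lost its call with 500 genes (0.098, adjusted p = 0.129) and with library totals (0.186, adjusted p = 0.0998; range -0.17 to 0.604).

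Same-numbered libraries showed residual correlations of -0.62 to 0.1, none of 18 pairs over 0.1, and 6 of 12 libraries correlated best with their own number. The values between the 2 differentiated groups were -0.62, -0.34 and -0.29. Residuals of those groups are shaped by the 2 doubted libraries, so the check cannot decide pairing there. A pairing by number was neither shown nor excluded. With the replicate block the counts were 7931, 7220, 2834, 0 and 747. Calls were lost for Tnfsf14 in control differentiation (adjusted p = 0.106, edgeR) and for Tnfrsf14 (0.0631) and Rn18s (0.0867) in LIGHT before. In the interaction they were lost for Rn18s (0.0731), U90926 (0.0824), Hmgcs1 (0.0786), Mcm3 (0.0737) and Scd2 (0.0823).

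For control differentiation, LIGHT differentiation and LIGHT before, 1 of the 10 splits gave as many genes (8307, 7612 and 3446; highest other 0 in each), too few splits for a share under 0.05. For LIGHT after, all 10 splits gave at least the labelled 0, with 5169 in the split that exchanges replicate 1 of the 2 groups. At this depth genes under 3 counts per library, such as Ucp1, cannot be compared.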

Other observations

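All results of this part were chosen only after the values were seen.

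Without the 2 doubted libraries, 2282 genes were called between the lines at both stages, 831 of them higher at both and 696 lower at both, against 429 and 476 for independent lists. Another 414 were higher before and lower after differentiation, and 341 the reverse. Among single genes with a large difference at both stages, some encode secreted or matrix proteins, a group not tested here as a set. Mmp9, a gelatinase, was higher by 2.23 before and 4.2 after in log2, Dcn by 1.97 and 1.74, Wnt4 by 2.74 and 1.73, the collagen Col11a1 by 2.69 and 1.58 and the lysophospholipase Enpp2 by 2.24 and 1.16. Timp3, an inhibitor of metalloproteinases, was lower (-2.37 and -2.98), as were Aebp1 (-1.91 and -2.4), the AP-1 component Fosl1 (-2.14 and -1.3), Fhl1 (-1.48 and -1.58) and the peptide hormone Cck (-2.52 and -2.25).

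Some genes outside the 19 lists were also higher at both stages. Frmpd4 was higher by 7.74 (SE 0.23) before and had a ratio of 469 after (95% counting interval 83.7 to 18600), Akr1c12 was higher by 3.73 (SE 0.19) and 3.59 (SE 0.25) and the glutamate receptor subunit Gria3 by 2.72 (SE 0.15) and 2.84 (SE 0.24), all in edgeR. The design has 1 line of each kind, so a difference between the lines that is not due to LIGHT was not tested and cannot be told apart from an effect of LIGHT.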
